A study of Mus musculus with 6 samples.

How the data were processed

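Argonaute (Ago) HITS-CLIP, in which RNA cross-linked to Ago proteins is recovered by immunoprecipitation and sequenced, was carried out on bone-marrow-derived macrophages of C57BL/6 mice. The labels give 6 libraries, 3 from wild-type (WT) mice and 3 from APOBEC1-deficient (KO) littermates. APOBEC1 is a cytidine deaminase that edits C to U in mRNA. The cells were grown with M-CSF and the immunoprecipitation used the Ago antibody 2A8, per the labels' protocols. Libraries were assigned to groups by the genotype field of the labels.

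Per the series design text, the authors split the reads by length into an mRNA pool and a miRNA pool, aligned them to the mouse build mm9, and joined overlapping mRNA reads into clusters with a minimum number of reads. A footprint was then taken around the peak of each cluster. The authors deposited Ago occupancy as a ratio, the footprint signal over the RNA-Seq expression of its transcript, per the series design text. Bowtie 0.12.8 and bedtools are named in the submitters' processing notes, the latter without a version. How the 3 libraries of a genotype were combined, how library size was handled, and the unit of the expression divisor are not given in the sources used here. The table holds 1 occupancy value per genotype, called the authors' value, and the number of libraries of each genotype that held the footprint. Each of the 6270 footprints was held by at least 2 libraries of 1 genotype, the authors' definition of high confidence per the series design text. The table gives no read counts, so the depth of the libraries is unknown, and no interval that needs depth is given. Of the KO values above 0, 33.3% were shared exactly with another footprint, against 18.6% of the WT values. Such sharing crossed genes. In KO 732 distinct values, and in WT 502, were held by footprints that did not all lie on the same gene. How these equal values arose is not given in the sources used here.

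Footprints were placed on the NCBIM37 genome (the same assembly as mm9) with the GENCODE vM1 annotation. Each footprint lay within the length of its chromosome. The strand came from the footprint identifier. Each footprint took the first class that it overlapped on its strand, in the order 3′ UTR, coding sequence, 5′ UTR, other exon and intron. Where it overlapped more than 1 gene of that class (17 footprints), the gene with the longest overlap was used. In 3 cases the annotation gave the same symbol to more than 1 gene identifier, and these were summed. Coordinates are mm9 and counted from 1. Sequences were fetched with pysam 0.24.0 after indexing with samtools 1.23.1.

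The log2 ratio of KO over WT was computed with a pseudocount of 0.00161, which is 50% of the smallest value above 0. Such ratios understate the difference of footprints with low values. With 1 combined value per genotype there is no test of KO against WT, no p-value and no SD between libraries. Differences therefore have no replicate check, and a 2-fold rule replaced a threshold on adjusted p. Gene values are sums over footprints. An occupancy listed at 0 was kept in medians and counts through the pseudocount, but no fold is given for it. Intervals of medians are 95% binomial intervals of order statistics over footprints. Intervals of shares are 95% Wilson intervals. Both describe the spread over footprints, which are not replicates.

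Lists of genes were fixed before the data were examined. There were 17, of which 13 had at least 6 footprints. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched in 10 bins of mean occupancy, as a description of these libraries. For miRNA seed sites, a 7-nt match to bases 2 to 8 of 22 miRNA families was counted in each footprint and in 20 shuffles that keep dinucleotide counts. The planned permutation test over footprints of the ratio with and without a site was not run, and the same percentile was used in its place. The planned correction over families and over lists was not made. After the data were examined, both percentiles were repeated with random sets also matched on G+C content (5 bins of occupancy by 10 of G+C, or 3 by 5 in the smallest set).

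Named footprints followed a rule fixed in advance. It took the 10 highest and 10 lowest ratios among footprints above 0 in both genotypes with a mean occupancy at or above the table median of 0.425, with 1 footprint per gene and a footprint without a gene counted by itself. It also took the 10 genes with the highest mean occupancy. These were ranked by their strongest single footprint and not by sums, and a footprint without a gene was counted by itself. The rule further took every measured gene of the edited-target list, and from each other list the 2 genes highest and the 2 lowest in KO, a few of which are not named in the text. The extremes among footprints found in all 6 libraries, and genes named outside these rules, were chosen after their values were seen.

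The percentile was tested on simulated data. Among random sets of 40 footprints, 4% of sets with no shift lay outside the central 95%, against 56% with a shift of 0.5 and 98% with a shift of 1 on the log2 scale. The simulated ratios were drawn independently from footprints above 0 in KO. They hold neither values listed at 0 nor footprints of 1 gene that move together, so these shares may differ for the gene lists. Alternatives covered the pseudocount, filters on low values, the gene as the unit, median centring, the rule for presence, and the site length. Filters on the number of libraries and on annotation were added after the data were examined. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.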

Results

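Ago footprints were compared between macrophages of WT and APOBEC1-deficient littermates, with 3 libraries per genotype combined by the authors into 1 occupancy value each. The 6270 footprints lay on 2223 genes, of which 1198 held at least 2. In all, 6063 footprints (96.7%) overlapped an annotated 3′ UTR on their own strand. Their lengths ran from 63 to 1092 nt with a median of 72 nt. Median occupancy was 0.377 in KO (quartiles 0.155 and 0.842) and 0.406 in WT (quartiles 0.187 and 0.813). In KO, 290 footprints were listed at 0, and none were in WT. The table gives no read counts, so the depth of each library is unknown. No difference between the genotypes given here has a replicate check. Coordinates are those of mouse build mm9.

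The targeted gene, Apobec1, carried 3 footprints in its 3′ UTR on chromosome 6, between 122527957 and 122528795 on the minus strand. Their summed occupancy was 0.312 in KO and 0.372 in WT, a log2 ratio of -0.25. The footprint at 122527957 to 122528023 was found in 3 KO and 2 WT libraries, with occupancies of 0.174 and 0.181. The labels do not say which part of the gene was removed, so Ago footprints in its 3′ UTR do not check the genotype.

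The strongest Ago footprints included those of the cell surface proteins C3ar1, Itga5 and Lair1 and of the secreted protein Plau, and they were high in both genotypes. C3ar1, a receptor for a complement fragment, had the highest mean occupancy, 46.3 in KO and 35.5 in WT, at 122798679 to 122798741 of chromosome 6 in its 3′ UTR. Cyth1, an exchange factor for ARF GTPases, followed with 45.8 in KO and 24.1 in WT (chromosome 11, 118025708 to 118025770). Plau, the urokinase plasminogen activator, had 27.9 in KO and 13.98 in WT, and the integrin Itga5 had 18.4 and 16.4. Lower values in KO than in WT were seen for H6pd, an enzyme of the endoplasmic reticulum (17.4 and 29.2), and for the nuclear long non-coding RNA Malat1 (13.1 and 29.9). Col4a3bp, which transfers ceramide, had 16.2 in KO and 17.8 in WT, Sbno1 had 14.1 and 11.6, and the inhibitory collagen receptor Lair1 had 10.4 and 12.8. The other footprint of the 10, at 117286008 to 117286072 of chromosome 7, overlapped no gene on its strand and lay 382 nt past the end of the kinase gene Wee1, with 28.2 in KO and 27.9 in WT. These 10 footprints were found in all 6 libraries.

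Whether occupancy as a whole was higher or lower without APOBEC1 was asked of the median log2 ratio over footprints. It was -0.04 (95% interval -0.08 to -0.00), and 48.7% of footprints (47.5% to 49.9%) were higher in KO. Among the 3135 footprints with a mean occupancy at or above the table median it was 0.07 (0.02 to 0.13), with 52.2% higher in KO, so the direction turned with this filter. Among the 5980 footprints above 0 in both genotypes it was 0.04 (-0.01 to 0.07), among the 2196 found in at least 2 libraries of both genotypes 0.42 (0.38 to 0.48), and among the 369 found in all 6 libraries 0.13 (0.03 to 0.18). The last 3 sets leave out footprints low in KO by construction, the 290 listed at 0 in KO or those found in few KO libraries. They therefore do not give the direction of the whole set. Of the whole set, 3753 footprints entered through at least 2 WT and fewer than 2 KO libraries, and 321 the other way round. Such entry favours values high in WT, so the whole set does not settle the direction either. Across footprints, KO and WT occupancy had a Spearman correlation of 0.612, which was 0.832 in the 2196 and 0.952 in the 369. Footprints are not independent replicates.

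**Figure D1:**
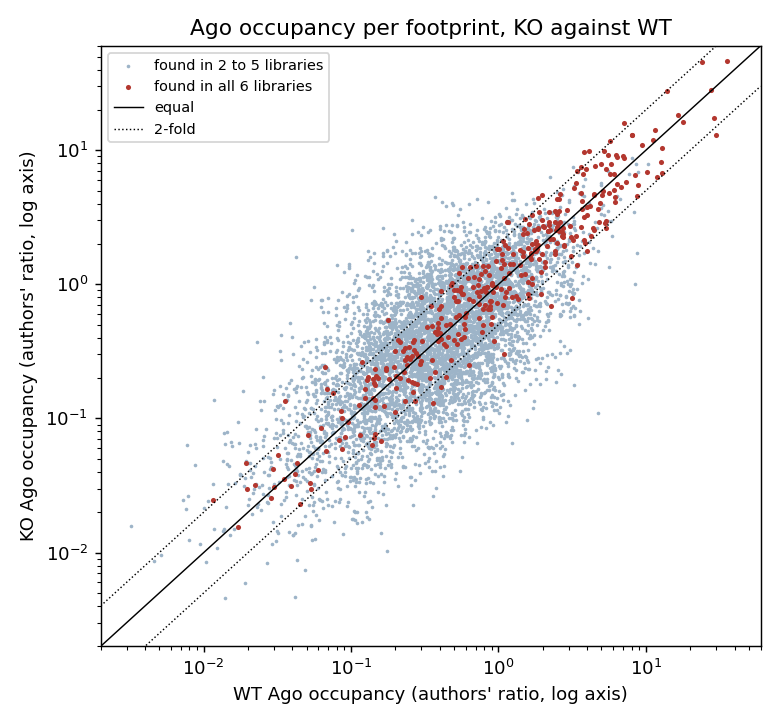
Ago occupancy in KO (vertical) against WT (horizontal), both the authors' ratio on log axes, for the 5980 footprints above 0 in both genotypes, 1 point each. The 369 footprints found in all 6 libraries (red) lie close to the line of equal values, with a Spearman correlation of 0.952, and the others spread more widely.

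Among the footprints with the highest KO to WT ratios were those of Snx30, a sorting nexin, and Smad4, the common mediator of TGF-β signalling. The 3′ UTR footprint of Snx30 (chromosome 4, 59916672 to 59916765) had 1.61 in KO and 0.0421 in WT, a log2 ratio of 5.20, and was found in 3 KO and 0 WT libraries. Smad4 had 0.963 in KO and 0.0564 in WT (4.06; chromosome 18, 73799477 to 73799556). An intronic footprint of Glb1, the lysosomal beta-galactosidase gene, had a ratio of 4.62. The ratio was 4.08 for Nipa2, 3.99 for the dynein regulator Pafah1b1, 3.86 for B230219D22Rik, 3.80 for the tyrosine phosphatase Ptpre, 3.76 for the ubiquitin ligase Ubr2, 3.75 for the heterochromatin protein Cbx5 and 3.73 for the small GTPase Rap2c. Among the lowest ratios, Dusp6, a phosphatase of ERK kinases, had 0.179 in KO and 3.24 in WT (-4.17; chromosome 10, 98729577 to 98729653, 3′ UTR). Son, a splicing cofactor, had 0.0654 and 1.23 (-4.20; chromosome 16, 91678655 to 91678721, 3′ UTR). The lowest ratio, -5.40, was that of a footprint on chromosome 5 (123183126 to 123183192) that overlapped no gene and lay 21 nt past the annotated end of the kinase gene Camkk2. Lower ratios were also found for Tmed7 (-3.97), the RNA-binding protein gene Hnrnpab (-3.82), Tanc1 (-3.71), the lysosomal sulfatase Ids (-3.68), the histone methyltransferase Nsd1 (-3.61), Osbpl2 (-3.55) and the cohesin subunit Stag2 (-3.46). None of the 10 footprints with the highest ratios was found in more than 1 WT library, and none of the 10 lowest in more than 1 KO library. The table gives values above 0 for footprints that no library of a genotype held, 1462 in KO and 29 in WT. Such values lie under 3 of the 10 highest ratios and 9 of the 10 lowest, and how they were made is not given in the sources used here. With a pseudocount of 1 the named ratios kept their direction but shrank. Snx30 went to 1.32, and Smad4 (0.89) and Osbpl2 (-0.95) fell short of 2-fold.

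A log2 ratio of at least 1 in either direction was reached by 1184 footprints higher and 1518 lower in KO, and by 259 genes higher and 397 lower of 2223. The excess of lower values came mostly from the footprints listed at 0 in KO. The selection through WT libraries described above applies to these counts too. Among footprints above 0 in both genotypes 1184 were higher and 1228 lower, and 272 genes were higher and 311 lower. Among those with a mean occupancy at or above the table median 656 were higher and 627 lower. With a pseudocount of 1 in place of 0.00161, 104 footprints were higher and 127 lower. Sets chosen by the number of libraries of both genotypes leave out footprints found in few KO libraries by construction. Among footprints found in at least 2 libraries of both genotypes the split was 575 higher and 110 lower. In those found in all 6 libraries it was 25 and 16 of 369. There, the highest ratios were those of Apoe, an apolipoprotein of macrophages (1.88; 0.135 in KO and 0.0355 in WT), the syndecan Sdc3 (1.84), Txnip, a thioredoxin inhibitor (1.61), the scaffold protein Iqgap1 (1.43) and the growth factor Igf1 (1.36; 9.74 and 3.80). The lowest were those of Zfp207 (-1.99; 0.786 and 3.14), the splicing regulator Mbnl1 (-1.83), the Hippo pathway kinase Stk4 (-1.71), the transporter Slco4a1 (-1.44) and Nckap1l, a haematopoietic subunit of the WAVE complex (-1.34).

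Footprints were found in fewer KO than WT libraries. At least 1 library of both genotypes held 4489 footprints, WT libraries alone held 1752 and KO libraries alone 29. At least 2 libraries held 5949 footprints in WT and 2517 in KO. Of the footprints qualified by WT, 36.9% were found in at least 2 KO libraries, and of those qualified by KO, 87.2% were found in at least 2 WT libraries. Both shares count the same 2196 footprints, so their difference restates the larger number qualified by WT. The share rose with occupancy in KO from 10.1% in the lowest of 10 occupancy bins to 90.0% in the highest, and in WT from 70.5% to 99.4%. Where occupancy above 0 counted as presence, 290 footprints were WT only and 0 KO only.

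**Figure D2:**
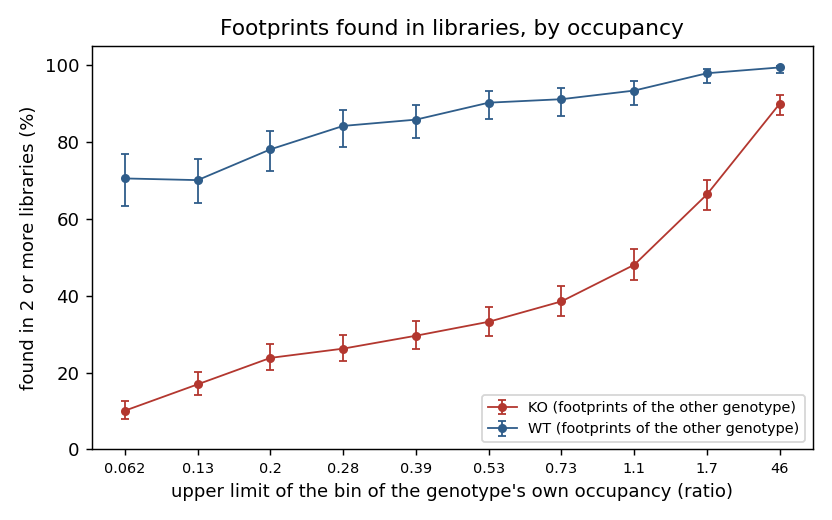
Share of footprints found in at least 2 libraries (vertical, percent, with 95% Wilson intervals) by bin of the genotype's own occupancy (horizontal, upper limit of each bin), for KO among footprints qualified by WT and for WT among footprints qualified by KO. KO lies below WT in all 10 bins, from 10.1% against 70.5% in the lowest to 90.0% against 99.4% in the highest. Over all bins both curves count the same 2196 footprints as found. The gap therefore follows from the larger number qualified by WT and does not compare detection at equal occupancy.

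The KO to WT ratio followed the base composition of the footprint. In the 627 footprints with the lowest G+C content (15.5% to 31.2%) the median log2 ratio was -0.82 (-0.99 to -0.65), and in the 627 with the highest (55.4% to 73.1%) it was 0.62 (0.51 to 0.71). Across footprints the Spearman correlation of G+C content and ratio was 0.325. It was 0.242 among footprints found in at least 2 libraries of both genotypes and 0.377 among those found in all 6. The share found in at least 2 KO libraries went from 21.7% to 59.3% between these sets, and in WT from 99.4% to 86.8%. By the entry rule, a footprint in fewer than 2 KO libraries is in at least 2 WT libraries. The WT share is thus held high where the KO share is low. The mean number of libraries went from 0.79 to 1.69 in KO and from 2.09 to 2.05 in WT. Percentiles matched on G+C content are therefore given beside those of the gene lists and seed sites, an alternative chosen after the data were examined.

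**Figure D3:**
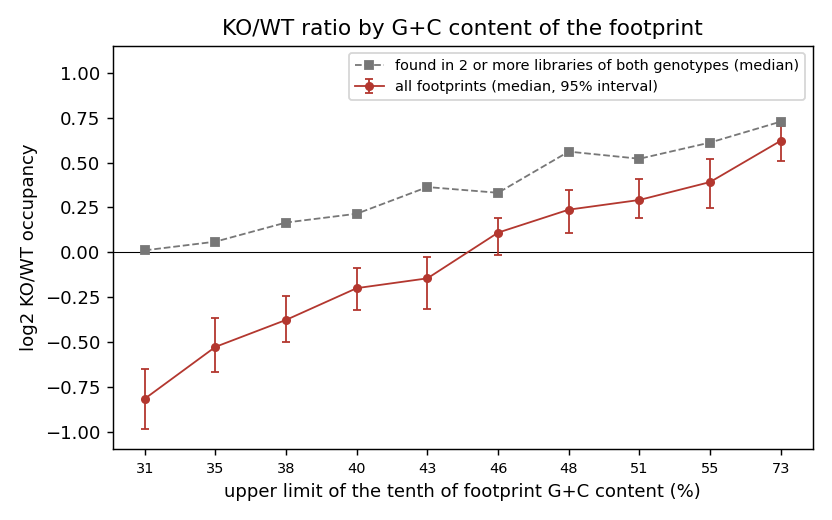
Median log2 KO/WT occupancy (vertical) in 10 bins of footprint G+C content (horizontal, upper limit of each bin in percent), for all footprints with 95% intervals (red) and for those found in at least 2 libraries of both genotypes (grey). The median goes from -0.82 to 0.62 over all footprints and from 0.01 to 0.73 in the grey set.

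Transcripts reported in earlier work on mouse tissues as C-to-U editing targets of APOBEC1 were taken as a list, fixed in advance from memory. The question was whether their Ago occupancy differed without the editing enzyme. Whether they are edited in these macrophages was not checked. Of 42 symbols, 16 genes were measured with 62 footprints, and 10 genes were higher and 6 lower in KO by summed occupancy. Higher values in KO were found for Mtmr2, a phosphoinositide phosphatase (0.89), Actr2, a subunit of the actin-nucleating complex (0.77; 5.75 in KO and 3.37 in WT over 9 footprints), the transcription factor Atf2 (0.72), Iqgap1 (0.58), the scavenger receptor Cd36 (0.50; 4.08 and 2.89), Sh3bgrl (0.49), Serinc1 (0.32), the amyloid precursor App (0.28), the trafficking GTPase Rab1 (0.25) and B2m, the light chain of MHC class I (0.18). Lower values were found for Anxa5 (-0.07), Cmtm6 (-0.20), the flippase subunit Tmem30a (-0.41), Usp25 (-0.52), Rnf128 (-0.61) and the selenoprotein Sep15 (-1.66; 0.0403 in KO and 0.131 in WT). Sh3bgrl and Rab1 were higher by sum only, as each had 1 footprint higher and 5 lower in KO. Of all 62 footprints, 33 were higher in KO. The median log2 ratio of the 62 footprints was 0.13 (-0.50 to 0.43), at percentile 87.0 of random lists of single footprints matched on occupancy. Their median G+C content was 35.9%, and among random lists matched on G+C content too (central 95% from -0.82 to -0.03) the same median stood at percentile 99.8. That percentile was 93.2 without Iqgap1, 95.7 without Serinc1 and at least 99.6 without any other single gene. It was 82.3 among the 29 footprints found in at least 2 libraries of both genotypes.

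None of the 13 lists lay outside the central 95% of random lists matched on occupancy, and with matching on G+C content only the edited-target list did. Inflammatory signalling had the highest percentile, 95.7 (96.1 with G+C matching), with 10 of 15 genes higher in KO. Traf3 (2.33; 2.90 in KO and 0.578 in WT) and the NF-κB subunit gene Nfkb1 (1.53) were highest, and the lipopolysaccharide receptor Tlr4 (-1.25; 2.89 and 6.88) and Nfkbiz (-0.39) lowest. Genes for proteins that bind AU-rich RNA stood lowest, with a median of -0.36 at percentile 2.51, at the edge of the range, at 13.3 with G+C matching, at 21.4 (median 0.20) among footprints found in at least 2 libraries of both genotypes and at 39.4 by strongest footprint. Of 8 measured, 2 were higher, Zfp36 (0.70) and Zfp36l1 (0.34), and 6 lower, with Zfp36l2 (-1.27) and Rbm47 (-0.46) lowest. These are sums. Single footprints went mostly the other way for Zfp36l1 (2 higher and 4 lower) and Rbm47 (2 higher and 1 lower). The splicing regulator Qk gave 26 of its 56 footprints. Lysosome and phagocytosis genes stood at percentile 94.5 (91.7 with G+C matching, and 2.09 among footprints found in at least 2 libraries of both genotypes), with 12 genes higher and 12 lower. Glb1 (2.86, a sum over 2 annotated genes of that name) and the cholesterol-binding Npc2 (0.83) were highest, and Gusb (-1.47) was among the lowest.

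Macrophage identity genes stood at percentile 44.9 (50.1 with G+C matching, 87.7 at a mean occupancy at or above the table median and 7.04 among footprints found in at least 2 libraries of both genotypes), with 10 higher and 12 lower. The Fc receptor Fcgr1 (0.73) and the transcription factor Maf (0.71) were highest, Emr1, which encodes F4/80 (-0.84), and Sirpa (-0.83) lowest. Lipid handling genes, at 55.9 (70.0), split into 6 and 6, with the sterol regulator Srebf1 (2.39) and Apoe (1.88) highest and the lipid droplet gene Plin2 (-2.16) among the lowest. Interferon response genes, at 79.5 (75.2; 96.7 with 3′ UTR footprints alone), had 8 higher and 10 lower, among them Ifnar2 (1.35) and Ifngr1 (1.16) at 1 end and Irf1 (-4.07; 0.0607 in KO, with 1 of its 2 footprints listed at 0, and 1.04 in WT) and Ifit3 (-3.05) at the other. Antigen presentation genes, at 73.8 (78.7), split into 4 and 4, from H2-Aa (2.29) and H2-K1 (0.48) to Calr (-1.17) and Pdia3 (-0.36). Genes of the miRNA machinery, at 78.4 (78.0), had 5 higher and 8 lower. With summed occupancy per gene their median went from 0.18 to -0.34, at percentile 10.1. The Ago gene Eif2c1 (0.94) and Tnrc6c (0.45) were highest, and Tnrc6a, which encodes an Ago partner protein (-2.17), and the deadenylase Cnot7 (-2.17) lowest.

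Cytoskeleton and adhesion genes stood at percentile 72.0 (85.3 with G+C matching, 98.8 at a mean occupancy at or above the table median and 4.92 with summed occupancy per gene), with 12 higher and 13 lower, from Actr2 (0.77) and Arpc5 (0.67) to Rac2 (-1.60) and Arpc2 (-1.40). Ubiquitin system genes, at 9.61 (25.5; 97.9 among the 8 footprints found in at least 2 libraries of both genotypes), had 7 higher and 10 lower, with Ube2k (1.34) and Fbxo11 (1.17) highest, Ube3a (-2.87) and Ube2g1 (-2.28) among the lowest, and Itch listed at 0 in KO. Cell cycle genes, at 41.8 (39.8), split into 6 and 6, with E2f1 (2.58) and Cdk2 (1.42) highest, Cdk4 (-1.43) and Cdkn1b (-1.35) low, and Rbl1 listed at 0 in KO. Classic miRNA targets, at 36.8 (26.7), had 6 higher and 10 lower, from E2f1 and Hmga1 (0.71) to the phosphatase Inpp5d (-1.97). Among the genes named from the lists, no KO library held a footprint of Plin2, Irf1, Cnot7, Ube3a, Ube2g1 or Cdk4. How their KO values above 0 were made is not given. No footprint of Traf3 or Srebf1 was found in more than 1 WT library. Lists for T and B cells, neutrophils and stromal fibroblasts had 0 genes measured, and the dendritic cell and osteoclast list had 1, Nfatc1 (0.46).

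**Figure D4:**
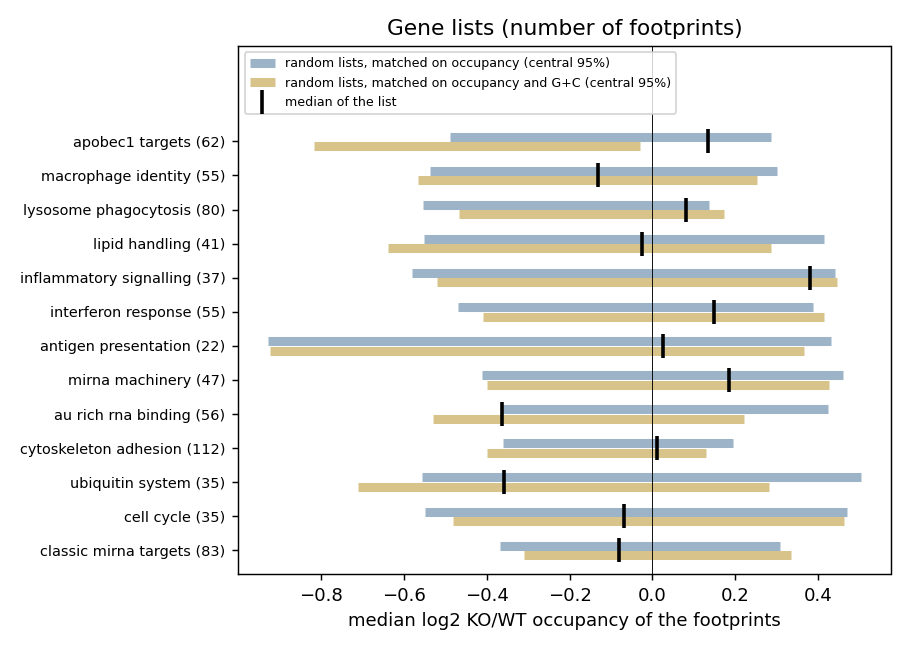
Median log2 KO/WT occupancy of the footprints of 13 gene lists (black marks; number of footprints in brackets) with the central 95% of 10000 random lists matched on occupancy (blue) or on occupancy and G+C content (yellow). The random lists are draws of single footprints and do not keep footprints of 1 gene together. With occupancy matching no list lies outside its range, and with G+C matching the edited-target list, at 0.13, lies above its range of -0.82 to -0.03.

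Sites for miRNA families were asked for in the footprint sequences, since Ago is guided by miRNAs. A 7-nt site for any of the 22 families was present in 1072 footprints, 17.1% (16.2% to 18.0%), against 13.6% on average and 14.6% at most in shuffled sequences and 14.1% in windows 50 nt away. For 9 families the share was above each of the 20 shuffles. The largest shares were those of miR-15/16 (1.99%; 1.20% shuffled), miR-27 (1.59%; 0.937%), miR-23 (1.52%; 0.931%) and miR-30 (1.12%; 0.699%), and the others were let-7, miR-142-3p, the miR-17 family, miR-22 and miR-103. Of these 9, miR-22 alone was less frequent in footprints (0.718%) than in windows 50 nt away (0.861%). The inflammation-linked miR-155 (0.654%; 0.528% shuffled) and the myeloid miR-223 (0.670%; 0.744%) did not exceed their highest shuffle. In the 2847 footprints of at most 70 nt, sites were most frequent at positions 28 to 36, with 108 against 54.5 in shuffles, and were at 33 against 34.6 at positions 55 to 63.

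Footprints with any of these sites had a median log2 KO/WT ratio of -0.03, and those without -0.04. Of the families, 4 lay outside the central 95% of random footprint sets matched on occupancy. Footprints with sites for miR-103 (median 0.66, 61 footprints, percentile 99.9) and miR-15/16 (0.29, 125 footprints, 98.9) were high in KO, and those for miR-23 (-0.36, 95 footprints, 1.63) and miR-181 (-0.40, 74 footprints, 1.74) low. The sites of miR-103 (ATGCTGC) and miR-15/16 (TGCTGCT) overlap, as do those of miR-23 (AATGTGA) and miR-181 (TGAATGT). A footprint can count in both families of a pair, so these are not 4 separate results. Among footprints found in at least 2 libraries of both genotypes, miR-103 (percentile 99.1) and miR-15/16 (99.0) lay outside, while miR-23 (63.9) and miR-181 (80.7) moved to the upper side. With G+C matching only miR-103 stayed outside, at 99.8, and with an 8-nt site it stood at 70.8 with 15 footprints. The 8-nt sites outside the range were those of miR-23 (-0.78, 33 footprints, percentile 0.49; 2.68 with G+C matching, and 2.55 with 11 footprints in at least 2 libraries of both genotypes) and miR-26 (-1.30, 20 footprints, 0.08; 0.26), whose 7-nt sites had a median of -0.36 and 0.10.

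**Figure D5:**
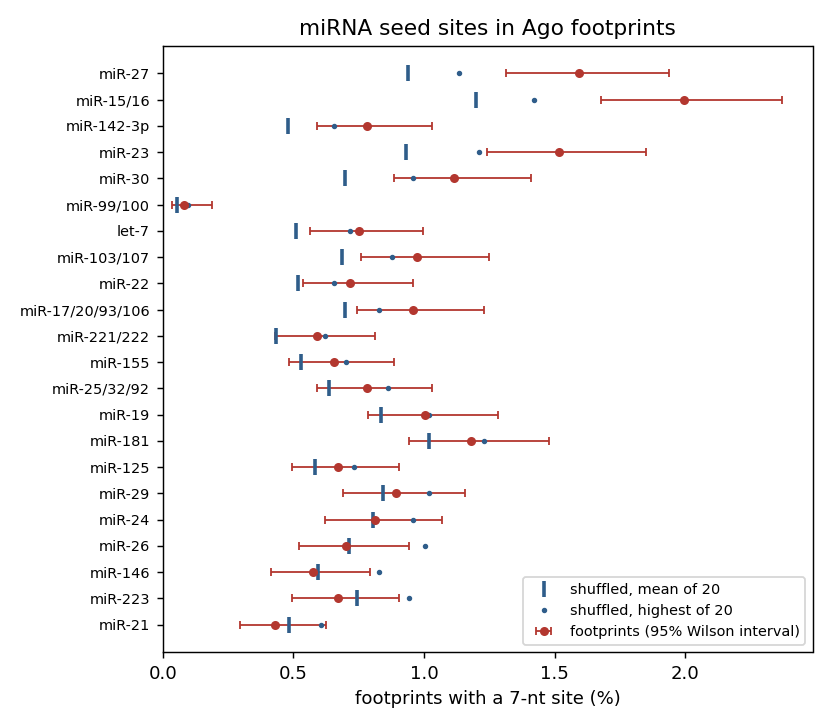
Share of footprints with a 7-nt site for each of 22 miRNA families (horizontal, percent; red points with 95% Wilson intervals), with the mean and the highest of 20 dinucleotide shuffles (blue). The share was above the highest shuffle for 9 families, among them miR-27 at 1.59% and miR-15/16 at 1.99%.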

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

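The filters on libraries and annotation, the matching on G+C content, and the presence rules of occupancy above 0 and of at least 2 libraries were chosen after the data were seen. No paired analysis was possible because the table has 1 combined value per genotype. For the same reason leaving out each library, scaling of single libraries and count-based tests were not run. Running without a filter on low values is the main setting, since each footprint meets the definition. With the smallest value above 0 as pseudocount, median centring or the restriction to 3′ UTR footprints, the 2-fold counts stayed within 1.5 times and the medians of the lists within their 95% intervals, though with 3′ UTR footprints the interferon median went from 0.15 to 0.36. Median centring sets the median of all footprints to 0 by construction, and detection and seed sites were not run under these 3. Of 258 values recomputed, 184 stayed within the limits set for their kind and 73 moved, and the edited-target percentile passed the central 95% with G+C matching. The causes were not tested except where the number of footprints fell.

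The median log2 ratio was 0.0387 for footprints above 0 in both genotypes, against -0.0383 for all, 0.0736 at a mean occupancy at or above the table median, 0.0143 for each gene's strongest footprint, 0.42 with at least 2 libraries of both genotypes and 0.13 in all 6 libraries. Footprints at least 2-fold higher and lower in KO numbered 104 and 127 with a pseudocount of 1, 656 and 627 with the mean occupancy filter, 575 and 110 with at least 2 libraries of both genotypes, and 25 and 16 in all 6 libraries. The filters on libraries leave out footprints found in few KO libraries by construction. Genes numbered 34 and 60 with a pseudocount of 1, fell from 397 to 224 lower with the mean occupancy filter and to 39 lower with at least 2 libraries of both, and were 11 and 12 in all 6 libraries. The edited-target median was 0.55 with the mean occupancy filter and 0.52 with at least 2 libraries of both genotypes. Lists outside the central 95% numbered 1 for footprints above 0 in both genotypes (AU-rich RNA binding, low), 1 with the mean occupancy filter (cytoskeleton and adhesion, high), 1 by strongest footprint (ubiquitin system, low), 2 with at least 2 libraries of both and 1 with G+C matching (edited targets, high). Those 2 changed sides: lysosome from percentile 94.5 to 2.09, ubiquitin system from 9.61 to 97.9. Over the alternatives with a percentile, the lists ranged as follows: edited targets 59.9 to 99.8, macrophage identity 7.04 to 87.7, lysosome 2.09 to 95.3, lipid handling 48.2 to 86.8, inflammatory signalling 58.9 to 96.8, interferon response 38.0 to 96.7, antigen presentation 37.9 to 78.7, miRNA machinery 10.1 to 79.0, AU-rich RNA binding 1.41 to 39.4, cytoskeleton and adhesion 4.92 to 98.8, ubiquitin system 1.22 to 97.9, cell cycle 25.9 to 87.6 and classic miRNA targets 21.9 to 45.0. Presence above the 10th percentile of occupancy gave 601 footprints WT only and 254 KO only. Counting genes gave 398 WT only, 9 KO only and 1816 both. Occupancy above 0 gave 290 and 0, and at least 2 libraries gave 3753, 321 and 2196. Families with seed sites outside the central 95% numbered 2 with 8-nt sites (miR-23, miR-26) and 1 with G+C matching (miR-103).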

Other observations

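The tests of detection at equal occupancy, of summed occupancy, of variance between genes, of 3 and 3 against 2 and 2 libraries and of single bases were chosen after the result was seen. The gene with the most footprints was Qk, which encodes an RNA-binding regulator of splicing, with 26 and a summed occupancy of 24.4 in KO and 33.6 in WT, the myo-inositol transporter gene Slc5a3 held 22 (19.3 and 24.4), and Tet3, a DNA demethylase gene, held 18 (27.7 and 27.3). Among genes with at least 3 footprints found in all 6 libraries, the log2 ratio of summed occupancy ran from -0.15 for Oas2, an antiviral sensor gene (4.23 in KO and 4.69 in WT), to 0.92 for Sdc3 (1.52 and 0.807). The actin regulator gene Arhgdia was next highest (0.76; 0.885 and 0.524), and all 6 of its footprints and all 8 of Sdc3 were higher in KO. Outside same-strand 3′ UTRs lay 207 footprints, of which 109 overlapped no gene. Of these 109, 28 lay opposite a 3′ UTR of the other strand. Malat1 held a further footprint in all 6 libraries, at 5802274 to 5802336 of chromosome 19, with 0.842 in KO and 1.58 in WT. The kinase gene Prkcb held an intronic footprint in all 6 (chromosome 7, 129774358 to 129774423) with 1.55 and 1.88.

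Fewer footprints were found in at least 2 KO libraries than in at least 2 WT libraries. Among the 1018 footprints whose KO and WT occupancies lay within 0.25 log2 units of each other, 44.4% were found in at least 2 KO libraries and 98.5% in at least 2 WT libraries (difference -54.1 percentage points, -57.6 to -50.8). That is close to the -54.7 points of all footprints, so the deficit was not limited to footprints with lower KO values, and lower detection in the KO libraries, as from lower depth, may account for it. Lower Ago occupancy as a whole in KO cannot be told apart from this, because the summed occupancies were nearly equal (log2 ratio -0.004) and scaling by the authors would also make them so. A first test of each idea was set aside after its result was seen: the bins of occupancy (median difference -53.7 points) because both shares count the same footprints, and the ratio of footprints found in at least 2 libraries of both genotypes (0.42, 0.38 to 0.48) because that set is selected on detection in KO, and effects of the genotype itself on detection stay open.

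Ratios of KO to WT spread widely between footprints. Genes held a share of 0.0382 of the variance (95% interval 0.0135 to 0.0624). A shift in the expression divisor of a transcript thus accounts for little if all footprints of a gene share 1 divisor. The sources used here do not state that they do, and many values were shared exactly by footprints of different genes. Few reads behind a footprint may account for more, since the SD in footprints found in 5 or 6 libraries was 0.659 times that in footprints found in 2 or 3 (0.601 to 0.717) at matched occupancy. Footprints found in few libraries often lack 1 genotype, which widens ratios by selection, and between 3 and 3 against 2 and 2 libraries the SD ratio was 0.740 (0.645 to 0.811). Differences between footprints due to the genotype were not tested, as no values per library were used.

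The ratio of KO to WT rose with the G+C content of the footprint. The relation held within genes (Spearman 0.255, 0.224 to 0.286). A bias of the expression divisor would not give this if all footprints of a gene share 1 divisor, which was assumed. A G+C bias of the CLIP fragments may explain the relation. The ratio followed the footprint's own G+C content and not that of windows 50 nt away (slope ratio -0.0453, -0.125 to 0.0586). An effect of APOBEC1 on the bound RNA itself would look alike and is confounded with genotype. Bases were unequal, as 10 points more C in place of U went with 0.40 (0.35 to 0.44), more G with 0.21 (0.14 to 0.27) and more A with -0.11 (-0.16 to -0.06), values that a bias on G+C alone does not give. Footprints within 100 nt of a 10-nt motif resembling the APOBEC1 mooring sequence had a median of -0.218. It lay inside the range of random sets matched on occupancy and G+C content (-0.54 to 0.05, percentile 53.4). It also lay inside that of sets matched on occupancy alone (-0.31 to 0.25, percentile 7.90). As a set, the footprints near the motif thus did not stand apart from others of like occupancy and G+C content. That cannot decide whether editing is the source of the relation, because these are a small part of all footprints and their editing was not checked. Editing and other effects of the genotype stay open and untested.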
